A study of Zea mays with 12 samples.

How the data were processed

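Messenger RNA was measured by sequencing in silks of maize inbred B73 in 4 groups of 3 libraries: uninoculated, fusarium, trichoderma and trichoderma_fusarium. Per the labels' protocols, plants grew in a greenhouse, RNA was extracted with Trizol, and libraries were read as pairs of 100 bases on an Illumina HiSeq. The deposited values were raw counts of reads per gene, 1 column for each of 12 libraries and 39625 gene IDs. Per the submitters' processing notes, base calls were made with CASAVA 1.8.2, reads were trimmed with Trimmomatic 0.30 and aligned with TopHat2 2.0.8, TopHat and Bowtie2, and the authors' counts were made with featureCounts. The genome build and annotation release are not given in the sources used here. Only maize gene IDs were in the table, so no fungal transcript was measured, and 8697 IDs had no count in any library.

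Gene names came from a table of RefSeq genes of the Zm-B73-REFERENCE-NAM-5.0 assembly that lists older gene IDs as synonyms. Of the 39625 IDs, 19060 matched at least 1 RefSeq gene and 18539 exactly 1; 521 matched several and were left unnamed, and 2672 had a symbol other than a locus number. Most of the genes tested therefore have no name here, and named genes are a selected part of them. Some symbols are shared by several genes and some genes by several IDs, so the ID of each named gene is given at its first mention. Reads that align equally well to paralogs, such as the chalcone synthase genes c2 and whp, tubulins or the actins, may be lost or divided among them, and this could not be seen in gene counts.

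Libraries were scaled with the trimmed mean of M-values (TMM) and genes filtered with filterByExpr on the 4 groups in edgeR 4.0.16, which left 20517 genes and removed 19108. A model with 4 groups and 8 residual degrees of freedom was fitted to all 12 libraries (quasi-likelihood, robust), and 6 contrasts were tested: fusarium, trichoderma and trichoderma_fusarium each against uninoculated, trichoderma_fusarium against fusarium and against trichoderma, and the interaction, the Fusarium response with Trichoderma minus that without. Adjusted p-values are from the Benjamini-Hochberg method over the genes of a contrast, with a threshold of 0.05. SE of a log2 fold change is its size divided by the square root of F. CPM are given as means ± SD over the 3 libraries of a group.

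A total of 32 gene lists were used, of which 28 had at least 5 tested members and were tested as sets with camera (preset correlation 0.01) and fry in limma 3.58.1, adjusted over the lists of a contrast. Camera was also run with the correlation between members estimated from the libraries. The 4 lists with fewer members (circadian clock, kernel and endosperm, peroxidases and pollen) are described by their genes. Before the data were examined, 36 lists had been set down by words in gene descriptions. The name table had symbols but no descriptions, so 32 lists were restated by symbol, 31 of them from the original 36 and redox enzymes added, after the names and library totals had been seen and before any test. Lists of receptor-like kinases, NLR proteins, cytochromes P450, glycosyltransferases and salicylic acid genes were left out. In place of families by description, 23 families of genes that share a symbol stem, each with at least 10 tested members, were tested with camera.

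The rule for named genes was also written before the data were examined. In each contrast it took the 8 largest rises and the 8 largest falls among genes past the threshold with a mean of at least 5 CPM, a symbol, and groups whose libraries do not overlap (which 10% of unchanged genes show with 3 against 3; not asked in the interaction), and up to 2 members of each list with the smallest adjusted p. Where no member passed, the most abundant could be given by its values. From these the text names a part in each contrast, and genes outside the rule are said to be so. The other genes that the rule gave are not reported here.

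Alternatives fixed before the data were examined were DESeq2 1.42.0 size factors, upper-quartile scaling, no filter, at least 1 CPM in 3 or more libraries, the DESeq2 Wald test, limma-voom, replicate number as a block, fits of only the groups compared, leaving out the 20 most abundant genes, and leaving out each of 12 libraries. Overlaps with each library left out were added later. The responses that share the uninoculated libraries were set against 20 simulated draws of unchanged groups. Results were also compared with all 10 splits of 6 libraries and with 100 relabellings for the interaction, the real ones included. The test was tried on simulated data with 200 genes changed: at 2-fold it recovered 67.3% of changed genes for fusarium against uninoculated (20166 genes tested), 72.9% for trichoderma against uninoculated (20160), 69.4% for trichoderma_fusarium against uninoculated (20185), 62.5% for trichoderma_fusarium against fusarium (20178) and against trichoderma (20144), and 32.7% for the interaction (20193). At 4-fold the lowest share was 94%, for the interaction. At 1.5-fold the share for the interaction was 10%, so the absence of a call there says little about small changes. False calls among unchanged genes numbered 11, 4, 13, 6, 10 and 8 in the 6 contrasts in the same order. With 3 libraries per group no test for a single deviating library was run. Analyses used R 4.3.3, Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.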

Results

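RNA was sequenced from the silks of B73 maize, the inbred line of the maize reference genome, in 4 groups of 3 libraries. The uninoculated group received no fungus. The fusarium group received Fusarium verticillioides, a fungus that causes ear rot and can enter the ear through the silks. The trichoderma group came from plants whose roots had been given Trichoderma atroviride, a soil fungus used against plant pathogens, and the trichoderma_fusarium group received both fungi. Trichoderma spores (2 ml) were applied to young roots 10 days after germination, Fusarium spores (2 ml) to the silks 4 days after these emerged, and silks were harvested 24 h after that. A silk age of 4 days is given for all 12 libraries. For silks without Fusarium no inoculum on the silks and no time after inoculation are given. A difference in silk age at harvest or in handling of the silks could therefore not be told apart from the response to Fusarium. The labels call the libraries biological replicates without saying which plants each came from, so p-values measure the spread between these libraries.

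Total counts per library ran from 4488397 to 5211130 in the uninoculated group and from 4335796 to 5497814 in the fusarium group. They ran from 4898517 to 5606391 in the trichoderma group and from 3872388 to 6075848 in the trichoderma_fusarium group. After filtering, 20517 of 39625 gene IDs were tested. Values in parentheses after a gene are its log2 fold change, the SE of that and its adjusted p. Component 1 of log2 CPM (counts scaled to a common library total), with 54.1% of the variance, parted the 6 libraries with Fusarium from the 6 without. Component 2, with 11.3%, set fusarium replicate 2 apart at -46.8, where the other 11 libraries lay between -15.1 and 33.2. Its counts differed from those of fusarium replicates 1 and 3 with a chi-square per degree of freedom of 6.99 and 9.49, against 1.86 to 3.75 in the other pairs of replicates. Relative to the mean of the other fusarium libraries, this library had lower median log2 CPM of chitinases and beta-1,3-glucanases (-0.944), PR proteins (-0.82), photosynthesis genes (-0.771) and lipid transfer and cuticle genes (-0.678). It was also lower for lipoxygenase and jasmonate synthesis genes (-0.621), glutathione transferases (-0.611) and phenylpropanoid genes (-0.608), against -0.00879 over all genes tested. The 2 genes tested that are listed as pollen markers differed by -0.74.

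**Figure D1:**
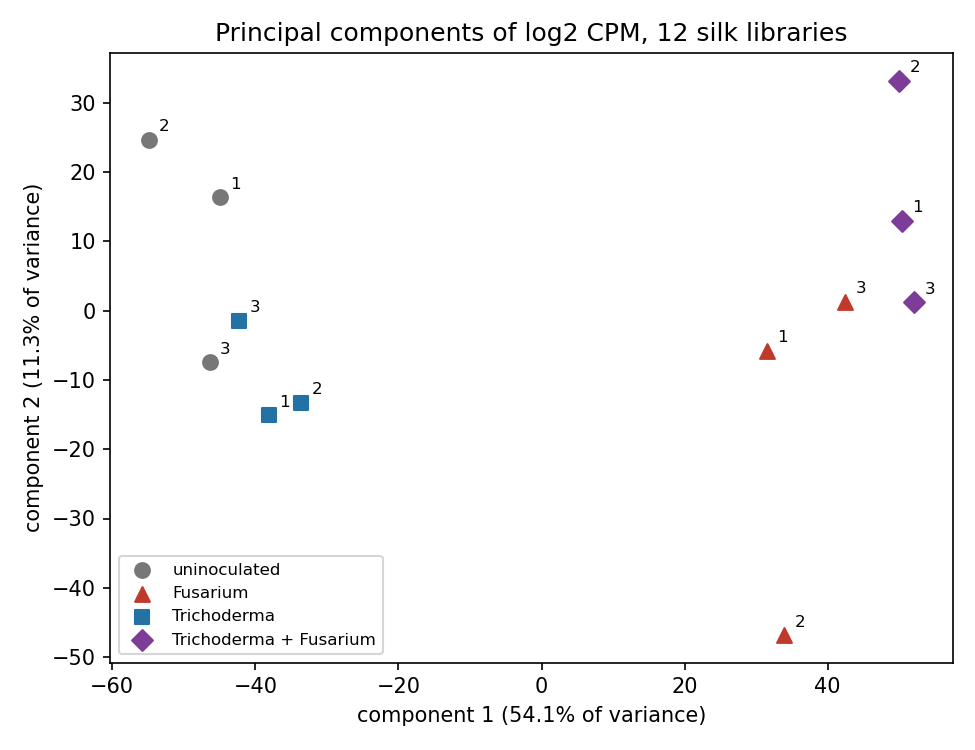
Libraries on components 1 (54.1% of the variance) and 2 (11.3%) of log2 CPM over the 20517 genes tested, each point 1 library with its replicate number and the marker of its group. The 6 libraries without Fusarium lie between -54.9 and -33.6 on component 1 and the 6 with Fusarium between 31.5 and 52.1.

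The comparison of fusarium with uninoculated silks asked how silks responded to Fusarium alone. CPPS2 (GRMZM2G044481), which makes ent-copalyl diphosphate for diterpenoid phytoalexins, rose from 1.1 ± 0.783 CPM (SD, n = 3) to 14.5 ± 3.79 CPM (log2 3.70, SE 0.38, adjusted p = 7.56e-07). MPI (GRMZM2G028393), the maize proteinase inhibitor, rose from 8.53 ± 2.77 to 97.2 ± 56 CPM (log2 3.49, SE 0.56, adjusted p = 0.00129). actin (GRMZM2G006765), an actin gene, fell from 366 ± 15.2 to 62.3 ± 9.77 CPM (log2 -2.55, SE 0.10, adjusted p = 3.2e-12). Profilin (GRMZM2G140455), an actin-binding protein, fell from 26.5 ± 3.74 to 1.31 ± 0.757 CPM (log2 -4.36, SE 0.27, adjusted p = 8.83e-10). In all, 4136 genes rose and 4069 fell past an adjusted p of 0.05 in edgeR's quasi-likelihood test. Of these 1196 rose and 953 fell by 2-fold or more.

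Other large rises were those of AR4 (GRMZM2G126062) (log2 fold change 3.70, SE 0.46), the high-affinity potassium transporter HAK5 (GRMZM2G084779) (3.23, SE 0.36) and the iron-phytosiderophore transporter ys1 (GRMZM2G156599) (3.08, SE 0.33). Next came the ethylene response factor ERF1 (GRMZM2G053503) (2.86, SE 0.26), CER1 (GRMZM2G099097), named for a wax alkane synthesis protein (2.71, SE 0.29), and PK1 (GRMZM2G328785) (2.65, SE 0.28). Their adjusted p-values ran from 1.43e-07 for ERF1 to 4.57e-05 for CER1. Among the large falls were MYBE1 (GRMZM2G145041) (log2 fold change -5.10, SE 0.46), the ROP GTPase gene rop6 (GRMZM2G176217) (-2.73, SE 0.29) and pcr1 (GRMZM2G084958) (-2.54, SE 0.25). They also included the myo-inositol-3-phosphate synthase gene INO1 (GRMZM2G155242) (-2.19, SE 0.12), AS2 (GRMZM2G118250) (-2.18, SE 0.32) and the chlorophyll a/b-binding protein gene cab-m1 (GRMZM2G351977) (-2.12, SE 0.24). Of these, INO1 had the smallest adjusted p (1.81e-10) and AS2 the largest (2.39e-05).

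Of 6 chitinases and beta-1,3-glucanases tested, enzymes that cut fungal cell walls, 4 rose and none fell, or 6 rose when adjusted over the list alone. The gene named chitinase (GRMZM2G453805) rose from 71.9 ± 20.9 to 345 ± 142 CPM (log2 2.26, SE 0.32, adjusted p = 0.00043). chiB (GRMZM2G005633) rose from 33 ± 12.6 to 132 ± 60.8 CPM (log2 1.98, SE 0.36, adjusted p = 0.00228). The list median was 1.82 (camera adjusted p = 0.00146; adjusted p = 0.607 with an estimated correlation). Fusarium replicate 2 differed from the other fusarium libraries by -0.944 on this list. Of 15 terpenoid phytoalexin genes, 8 rose and 1 fell (10 and 1 adjusted over the list alone). The median was 0.55 (camera adjusted p = 0.00228; adjusted p = 0.199 with an estimated correlation). The member that fell was fps (GRMZM2G168681), farnesyl pyrophosphate synthase (log2 -1.61, SE 0.13, adjusted p = 2.52e-08), which also feeds sterol synthesis. Of 17 senescence and autophagy genes, 10 rose and none fell (11 adjusted over the list alone). The median was 0.40 (camera adjusted p = 0.002; adjusted p = 0.199 with an estimated correlation). Examples were Atg8b (GRMZM2G419694), an autophagosome protein (log2 0.78, SE 0.10, adjusted p = 5.76e-06), and see1 (GRMZM2G038636), a cysteine protease of senescing leaves (log2 0.53, SE 0.09, adjusted p = 0.000148). Of 65 NAC, MYB and AP2/ERF transcription factors, 26 rose and 8 fell. The median was 0.30 (camera adjusted p = 0.0284; adjusted p = 0.7 with an estimated correlation). NAC61 (GRMZM2G003715) was among the rises (log2 1.23, SE 0.12, adjusted p = 2.2e-07). The call of this list was lost without uninoculated replicate 3 (adjusted p = 0.0569), fusarium replicate 1 (adjusted p = 0.0591) or fusarium replicate 3 (adjusted p = 0.0787).

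Of 36 ribosomal protein genes, 29 fell and 1 rose (31 and 1 adjusted over the list alone). The median was -0.65 (camera adjusted p = 2.37e-12; adjusted p = 0.436 with an estimated correlation). arpp40 (GRMZM2G126821) was among the falls (log2 -0.85, SE 0.09, adjusted p = 4.92e-07). Of 24 genes often used as references (actins, tubulins, GAPDH, ubiquitin and EF1-alpha), 16 fell and 3 rose. The median was -0.46 (camera adjusted p = 2.53e-06; adjusted p = 0.199 with an estimated correlation). Actin-7 (GRMZM2G082484) fell from 295 ± 7.63 to 91.3 ± 11.7 CPM (log2 -1.69, SE 0.10, adjusted p = 4.02e-10). Of 27 histone and DNA replication genes, 15 fell and 2 rose. The median was -0.50 (camera adjusted p = 0.000269; adjusted p = 0.199 with an estimated correlation). PCNA (GRMZM2G030523), the sliding clamp of DNA polymerase, fell (log2 -0.96, SE 0.11, adjusted p = 1.59e-06). The cyclin gene Cyclin-SDS (GRMZM2G093157) rose (log2 1.48, SE 0.27, adjusted p = 0.000211). Of 30 cell wall genes, 15 fell and 2 rose (15 and 3 adjusted over the list alone). The median was -0.30 (camera adjusted p = 0.0184; adjusted p = 0.654 with an estimated correlation). The cellulose synthase genes CesA-4 (GRMZM2G424832) (log2 -1.16, SE 0.11, adjusted p = 1.36e-07) and CesA-8 (GRMZM2G177631) (log2 -0.72, SE 0.10, adjusted p = 9.25e-06) fell. Of 16 photosynthesis genes, listed as markers of green tissue, 9 fell and 2 rose (9 and 3 adjusted over the list alone). The median was -0.48 (camera adjusted p = 0.00639; adjusted p = 0.7 with an estimated correlation). Fusarium replicate 2 differed by -0.771 on this list, whose call was lost with fry (adjusted p = 0.0537). Of the genes listed as pollen markers 2 were tested and both fell, Profilin and PRO4 (GRMZM2G108780), a profilin at 953 ± 36.5 CPM in uninoculated silks (log2 -0.87, SE 0.11, adjusted p = 3.82e-06). Whether either gene marks pollen in these libraries was not tested, so their falls do not show a loss of pollen.

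The other lists were not called with camera, and most held genes that moved both ways. With fry, benzoxazinoid (adjusted p = 0.0447), heat shock, sugar transport and calcium signalling genes (adjusted p = 0.00775 each) were called as lower. Of 10 benzoxazinoid genes, which make the defence compounds DIMBOA and its relatives, 4 rose and 5 fell (median -0.31, mean 0.19), with bx6 (GRMZM6G617209) (log2 -1.78, SE 0.15, adjusted p = 5.58e-08) and BX5 (GRMZM2G063756) (log2 -1.37, SE 0.15, adjusted p = 1.87e-06) among the falls. Of 18 flavonoid and maysin genes, 6 fell and 1 rose, including whp (GRMZM2G151227), a chalcone synthase gene (log2 -1.49, SE 0.17, adjusted p = 1.13e-05). Of 5 PR proteins, 4 rose, among them PR10 (GRMZM2G112524) (log2 2.08, SE 0.34, adjusted p = 0.000129), and prp2 (GRMZM2G102356) fell (log2 -2.06, SE 0.19, adjusted p = 4.12e-06). On this list fusarium replicate 2 differed by -0.82 from the other fusarium libraries. Of 17 lipoxygenase and jasmonate synthesis genes, 4 rose and 7 fell, with opr5 (GRMZM2G087192) up (log2 0.67, SE 0.11, adjusted p = 8.35e-05) and lox1 (GRMZM2G156861) down (log2 -1.26, SE 0.20, adjusted p = 0.000209). The counts that rose and fell were 5 and 1 of 15 jasmonate signalling genes, 3 and 1 of 11 proteinase inhibitors and 6 and 10 of 24 heat shock genes. They were 2 and 6 of 13 sugar transport and cleavage genes, 5 and 3 of 13 phenylpropanoid and lignin genes and 5 and 8 of 21 glutathione transferases. TIFY16 (GRMZM2G101769), of the JAZ repressor family, rose (log2 0.90, SE 0.15, adjusted p = 0.000142). hsp101 (GRMZM2G360681), a disaggregating chaperone, fell (log2 -1.40, SE 0.14, adjusted p = 8.34e-07), and so did the sucrose synthase gene sus1 (GRMZM2G152908) (log2 -1.07, SE 0.10, adjusted p = 2.04e-07). cad1 (GRMZM2G046070), cinnamyl alcohol dehydrogenase, fell (log2 -1.32, SE 0.11, adjusted p = 7.16e-08), as did the glutathione transferase gene gst12 (GRMZM2G096269) (log2 -1.38, SE 0.23, adjusted p = 0.000129).

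The remaining lists had 6 and 3 of 19 abscisic acid, dehydrin and LEA genes up and down, 8 and 7 of 42 auxin genes, 2 and 4 of 12 brassinosteroid and sterol genes, and 6 and 12 of 29 calcium signalling genes. There were 1 and 1 of 5 ethylene genes, 8 and 4 of 24 gibberellin and cytokinin genes, 2 and 3 of 8 lipid transfer and cuticle genes, 3 and 7 of 22 redox enzymes and 4 and 1 of 12 WRKY factors. SnRK2.6 (GRMZM2G130018), an abscisic acid response kinase, rose (log2 0.78, SE 0.11, adjusted p = 1.4e-05). HK1b2 (GRMZM5G833140), a cytokinin receptor kinase by name, rose (log2 1.44, SE 0.14, adjusted p = 7.29e-07). fae1 (GRMZM2G022558), of very-long-chain fatty acid elongation, fell (log2 -1.53, SE 0.11, adjusted p = 8.98e-09). dhar2 (GRMZM2G005710), dehydroascorbate reductase, fell (log2 -1.50, SE 0.18, adjusted p = 4.35e-06). Some lists had too few members for a set test. The 3 clock genes tested rose, among them the GIGANTEA genes gigz1b (GRMZM5G844173) (log2 0.96, SE 0.13, adjusted p = 2.29e-05) and GI (GRMZM2G107101) (log2 0.66, SE 0.11, adjusted p = 0.000128). None of 4 peroxidases was called. Of 4 kernel and endosperm markers 1 rose, GLB1 (GRMZM2G067402), a globulin, from 0.982 ± 0.786 to 5.5 ± 2.45 CPM (log2 2.47, SE 0.54, adjusted p = 0.00182). The other that changed, the basal endosperm marker EBE-1 (GRMZM2G129157), fell (log2 -0.51, SE 0.19, adjusted p = 0.0337). Without uninoculated replicates 1 and 2 or fusarium replicates 2 and 3 the adjusted p of EBE-1 was 0.0806, 0.0957, 0.11 and 0.0662.

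**Figure D2:**
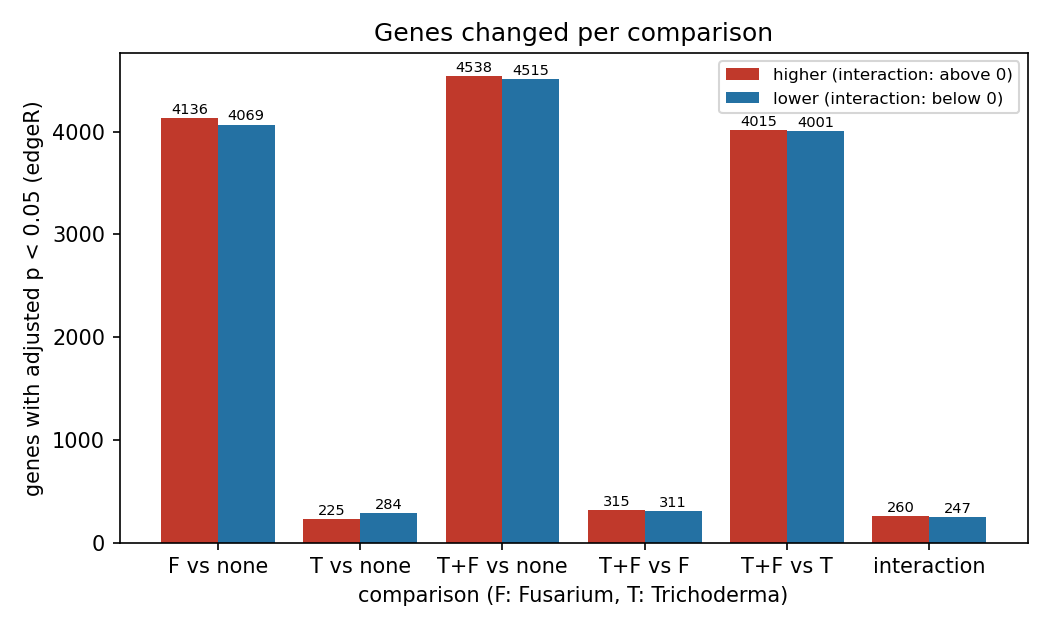
Number of genes past an adjusted p of 0.05 in edgeR's quasi-likelihood test (vertical axis) in each of the 6 comparisons (horizontal axis), those higher and those lower as separate bars. The bars stand at 4136 higher and 4069 lower with Fusarium alone, 4538 higher and 4515 lower with both fungi against uninoculated silks and 225 higher and 284 lower with Trichoderma alone. The interaction has 260 above and 247 below 0.

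The comparison of trichoderma with uninoculated silks asked what root inoculation left in silks that were not given Fusarium. Of 24 heat shock genes 6 fell, and of 36 ribosomal protein genes 18 fell. Camera called both lists as lower, but not with an estimated correlation (adjusted p = 0.329 and adjusted p = 0.383). Hsp70 (GRMZM2G310431), a chaperone gene, fell from 216 ± 38 to 94.2 ± 7.4 CPM (log2 -1.20, SE 0.13, adjusted p = 6.22e-05). The small heat shock protein gene hsp22 (GRMZM2G007729) fell from 19.9 ± 4.8 to 7.35 ± 0.152 CPM (log2 -1.44, SE 0.21, adjusted p = 0.00128). TPS17 (GRMZM2G010356), also named EDS, a sesquiterpene synthase gene, rose from 56.9 ± 11.1 to 117 ± 8.26 CPM (log2 1.04, SE 0.13, adjusted p = 0.000385). In edgeR's quasi-likelihood test 225 genes rose and 284 fell. Of these 60 and 34 changed by 2-fold or more, and 3057 genes had an unadjusted p under 0.05.

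Other genes with large rises were go1 (GRMZM2G129246), glycolate oxidase (log2 1.38, SE 0.20, adjusted p = 0.00128), and the nitrate transporter gene NRT1.2 (GRMZM5G811593) (log2 0.91, SE 0.22, adjusted p = 0.0307). Also higher were the photosystem I gene psad1 (GRMZM2G024150) (log2 0.91, SE 0.22, adjusted p = 0.0425), the thiamine thiazole synthase gene thi1-2 (GRMZM2G074097) (log2 0.89, SE 0.21, adjusted p = 0.0349) and the lipid transfer protein gene plt1 (GRMZM2G101958) (log2 0.82, SE 0.18, adjusted p = 0.0344). Large falls included hsp18f (GRMZM2G083810) (log2 -1.34, SE 0.20, adjusted p = 0.00128) and gols2 (GRMZM5G872256), galactinol synthase (log2 -1.08, SE 0.25, adjusted p = 0.0238). Further falls were those of hsp1 (GRMZM5G802801) (log2 -1.07, SE 0.22, adjusted p = 0.0135) and PMP3 (GRMZM2G477325) (log2 -0.73, SE 0.12, adjusted p = 0.00305). Of 36 ribosomal protein genes, 18 fell and none rose (29 adjusted over the list alone). The median was -0.39 (camera adjusted p = 8.02e-22; adjusted p = 0.383 with an estimated correlation). rps4 (GRMZM2G035017), of this list, fell from 349 ± 17.9 to 246 ± 16.4 CPM (log2 -0.50, SE 0.09, adjusted p = 0.00409). Of 24 heat shock and chaperone genes, 6 fell and none rose (10 and 2 adjusted over the list alone). The median was -0.23 (camera adjusted p = 2.94e-05; adjusted p = 0.329 with an estimated correlation). Of 18 flavonoid and maysin genes, 1 rose and none fell (5 and 1 adjusted over the list alone). The median was 0.25 (camera adjusted p = 0.0225; adjusted p = 0.936 with an estimated correlation). That gene was sm1 (GRMZM2G031311), salmon silks 1, of the synthesis of the silk flavone maysin, up from 775 ± 54.5 to 1100 ± 51 CPM (log2 0.50, SE 0.09, adjusted p = 0.00691; adjusted p = 0.0613 without uninoculated replicate 1 and 0.0705 without trichoderma replicate 2). The list call was lost without uninoculated replicate 3 (adjusted p = 0.249) and with fry (adjusted p = 0.565).

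The clock genes GI (log2 0.62, SE 0.11, adjusted p = 0.0064) and gigz1b (log2 0.53, SE 0.13, adjusted p = 0.0429) rose. Without uninoculated replicate 1, uninoculated replicate 2 or trichoderma replicate 1 the adjusted p of GI was 0.0558, 0.0577 and 0.0557. The benzoxazinoid gene BX4 (GRMZM2G172491) (log2 0.62, SE 0.14, adjusted p = 0.0232) and the Rubisco small subunit gene rbcS (GRMZM2G098520) (log2 0.53, SE 0.13, adjusted p = 0.0349) rose. The superoxide dismutase gene Sod4A (GRMZM2G058522) (log2 -0.55, SE 0.12, adjusted p = 0.0205), the tubulin gene tub6 (GRMZM2G071790) (log2 -0.40, SE 0.10, adjusted p = 0.0418) and the peroxidase gene PER42 (GRMZM2G126261) (log2 -2.39, SE 0.54, adjusted p = 0.0232) fell. None of the 6 chitinases and beta-1,3-glucanases, 5 PR proteins, 12 WRKY factors or 15 jasmonate signalling genes passed. chiA (GRMZM2G051943), a chitinase, had 585 ± 142 CPM in uninoculated and 391 ± 66.4 CPM in trichoderma silks (adjusted p = 0.529). The count of 509 genes fell to 79 without trichoderma replicate 2, 96 without uninoculated replicate 1, 102 without uninoculated replicate 2 and 110 without trichoderma replicate 1. More genes rose than fell without uninoculated replicate 1 (58 and 38), trichoderma replicate 1 (68 and 42) or trichoderma replicate 2 (48 and 31), against 148 and 317 without uninoculated replicate 3. The count came to 1141 without fusarium replicate 2, 802 with no filter and 1088 in a fit of the 6 libraries compared. Of the 33 genes the naming rule gave, 8 kept their call in all alternatives that tested them, among them go1, TPS17, hsp22, hsp18f, Hsp70, PMP3 and rps4. The call was lost by 25, 23, 13, 23, 24 and 16 of them without uninoculated replicates 1, 2 and 3 and trichoderma replicates 1, 2 and 3. Without fusarium replicate 1 and trichoderma_fusarium replicates 1, 2 and 3 it was lost by 9, 12, 4 and 8.

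Silks with both fungi were also set against uninoculated silks. PR-5 (GRMZM2G402631), a thaumatin-like protein gene, rose from 25.2 ± 5.89 to 223 ± 25.2 CPM (log2 3.14, SE 0.33, adjusted p = 4.45e-05). The gene named chitinase rose from 71.9 ± 20.9 to 541 ± 75.9 CPM (log2 2.91, SE 0.32, adjusted p = 6.79e-05). The chalcone synthase gene whp fell from 216 ± 11 to 29.7 ± 5.51 CPM (log2 -2.86, SE 0.19, adjusted p = 3.03e-08). The expansin gene expa2 (GRMZM2G105844) fell from 19.5 ± 1.84 to 2.64 ± 1.17 CPM (log2 -2.95, SE 0.25, adjusted p = 2.24e-08). In all 4538 genes rose and 4515 fell. By 2-fold or more 1572 rose and 1286 fell.

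Large rises were also seen for AR4 (log2 fold change 3.85, SE 0.45), GLB1 (3.36, SE 0.50), ys1 (3.19, SE 0.32), CPPS2 (3.16, SE 0.40) and MPI (3.14, SE 0.56), with adjusted p-values from 2.37e-07 for ys1 to 0.00197 for MPI. Large falls were those of prp2 (log2 fold change -3.31, SE 0.21), Profilin (-3.20, SE 0.23), actin (-3.04, SE 0.11), the tubulin gene TUB1 (GRMZM2G164696) (-2.77, SE 0.19) and gst12 (-2.63, SE 0.27), with adjusted p-values from 4.34e-13 for actin to 3.18e-07 for gst12. All 6 chitinases and beta-1,3-glucanases tested rose. The median was 2.12 (camera adjusted p = 0.000154; adjusted p = 0.445 with an estimated correlation). Among them chiA went from 585 ± 142 to 2860 ± 361 CPM (log2 2.29, SE 0.38, adjusted p = 0.0013). Of 15 terpenoid phytoalexin genes, 11 rose and 1 fell. The median was 0.73 (camera adjusted p = 0.000515; adjusted p = 0.163 with an estimated correlation). TPS17 rose (log2 1.65, SE 0.13, adjusted p = 1.36e-08) and fps fell (log2 -2.18, SE 0.14, adjusted p = 6.97e-10). Of 17 senescence and autophagy genes, 13 rose and none fell. The median was 0.57 (camera adjusted p = 4.15e-05; adjusted p = 0.12 with an estimated correlation). The protease gene see1 rose (log2 0.83, SE 0.09, adjusted p = 5.63e-07). Of 15 jasmonate signalling genes, 5 rose and none fell. The median was 0.49 (camera adjusted p = 0.0397; adjusted p = 0.537 with an estimated correlation). TIFY16 (log2 1.27, SE 0.15, adjusted p = 2.12e-06) and TIFY27 (GRMZM2G089736) (log2 0.78, SE 0.12, adjusted p = 2.68e-05), both of the JAZ repressor family, rose. Without some libraries the call of this list was lost, namely uninoculated replicate 3 (adjusted p = 0.0586) or trichoderma_fusarium replicate 2 (adjusted p = 0.0979).

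Of 36 ribosomal protein genes, 28 fell and 1 rose. The median was -0.64 (camera adjusted p = 1.05e-09; adjusted p = 0.446 with an estimated correlation). rps12 (GRMZM2G063340) fell (log2 -1.02, SE 0.10, adjusted p = 1.4e-07). Of 24 reference genes, 16 fell and 4 rose. The median was -0.63 (camera adjusted p = 8.1e-06; adjusted p = 0.229 with an estimated correlation). The tubulin gene tub5 (GRMZM2G133802) fell from 516 ± 48.7 to 145 ± 13.7 CPM (log2 -1.83, SE 0.10, adjusted p = 2.6e-10). Both tested genes listed as pollen markers fell, Profilin and PRO4 (log2 -0.85, SE 0.11, adjusted p = 2.99e-06), with a median of -2.03. Of 4 kernel and endosperm markers GLB1 and oleosin (GRMZM2G333069) rose (log2 1.45, SE 0.35, adjusted p = 0.00231) and 1 fell, with a median of 0.924. Of 27 histone and DNA replication genes, 17 fell and 2 rose (18 and 2 adjusted over the list alone). The median was -0.605 (camera adjusted p = 8.91e-05; adjusted p = 0.203 with an estimated correlation). The histone gene his2b2 (GRMZM2G119071) fell (log2 -1.05, SE 0.16, adjusted p = 8.2e-05). Of 30 cell wall genes, 17 fell and 1 rose. The median was -0.54 (camera adjusted p = 8.91e-05; adjusted p = 0.285 with an estimated correlation). CesA-4 fell (log2 -1.46, SE 0.11, adjusted p = 4.78e-09). Of 18 flavonoid and maysin genes, 10 fell and 1 rose. The median was -0.64 (camera adjusted p = 0.00314; adjusted p = 0.537 with an estimated correlation). sm2 (GRMZM2G180283), salmon silks 2, the rhamnosyltransferase of maysin synthesis, fell from 534 ± 51.7 to 275 ± 40.6 CPM (log2 -0.96, SE 0.13, adjusted p = 1.81e-05). The other lists were not called with camera. With fry, benzoxazinoid (adjusted p = 0.00347), heat shock and sugar transport (adjusted p = 0.00664 each), calcium signalling (adjusted p = 0.0174) and brassinosteroid and sterol genes (adjusted p = 0.0211) were called as lower. It called as higher PR proteins (adjusted p = 0.0242), WRKY factors (adjusted p = 0.0217), NAC, MYB and AP2/ERF factors (adjusted p = 0.0415) and proteinase inhibitors (adjusted p = 0.0211). So it did abscisic acid, dehydrin and LEA genes (adjusted p = 0.00664) and gibberellin and cytokinin genes (adjusted p = 0.00645). In these and other lists, BX5 (log2 -2.51, SE 0.17, adjusted p = 3.18e-09), the chaperone gene bip1 (GRMZM2G114793) (log2 -1.19, SE 0.11, adjusted p = 6.15e-08), cad1 (log2 -2.05, SE 0.12, adjusted p = 4.68e-10) and sus1 (log2 -1.17, SE 0.10, adjusted p = 3.56e-08) fell. The thaumatin-like gene Zlp (GRMZM2G374971) (log2 2.06, SE 0.22, adjusted p = 1.56e-05), WRKY29 (GRMZM2G040298) (log2 2.06, SE 0.32, adjusted p = 3.97e-05) and the lipoxygenase gene lox9 (GRMZM2G017616) (log2 0.86, SE 0.12, adjusted p = 9.19e-06) rose.

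The comparison of trichoderma_fusarium with fusarium silks asked what root Trichoderma changed among silks that were all given Fusarium. Some flavonoid (6 of 18), cell wall (3 of 30) and benzoxazinoid genes (2 of 10) fell. Camera called these lists as lower, but not with an estimated correlation (adjusted p = 0.679, 0.576 and 0.701). An ethylene response factor that rose with Fusarium alone stood near its uninoculated level. That gene, ERF1, had 2.09 ± 0.734 CPM in uninoculated, 15.5 ± 2.42 CPM in fusarium and 1.86 ± 0.626 CPM in trichoderma_fusarium silks (log2 -3.09, SE 0.27, adjusted p = 2.02e-06). A further AP2/ERF gene, EREB179 (GRMZM2G129674), fell from 11.8 ± 4.14 to 2.58 ± 0.839 CPM (log2 -2.15, SE 0.35, adjusted p = 0.00144). asn2 (GRMZM2G093175), asparagine synthetase, rose from 27.9 ± 4.64 to 52.4 ± 7.17 CPM (log2 0.92, SE 0.15, adjusted p = 0.00148). In all, 315 genes rose and 311 fell in edgeR's quasi-likelihood test. The balance moved with the library left out. Without fusarium replicate 2, 256 rose and 373 fell, and without fusarium replicate 3, 567 rose and 410 fell. Without trichoderma_fusarium replicate 2, 106 rose and 149 fell. Of the 626 genes, 444, 551 and 248 were called again. By 2-fold or more 83 rose and 97 fell, and 3425 had an unadjusted p under 0.05.

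Of 18 flavonoid and maysin genes, 6 fell and none rose (9 and 1 adjusted over the list alone). The median was -0.58 (camera adjusted p = 5.69e-05; adjusted p = 0.679 with an estimated correlation). The gene sm1 fell from 895 ± 91.3 to 508 ± 31.5 CPM (log2 -0.82, SE 0.09, adjusted p = 4.78e-05). The chalcone synthase gene whp fell from 76.9 ± 21.8 to 29.7 ± 5.51 CPM (log2 -1.37, SE 0.19, adjusted p = 0.00113). Fusarium replicate 2 differed by -0.469 from the other fusarium libraries on this list. Of 30 cell wall genes, 3 fell and none rose (5 adjusted over the list alone). The median was -0.19 (camera adjusted p = 5.95e-05; adjusted p = 0.576 with an estimated correlation). The expansin genes expa2 (log2 -2.39, SE 0.26, adjusted p = 2.62e-05) and expa1 (GRMZM2G339122) (log2 -0.94, SE 0.13, adjusted p = 0.000364) fell. Of 10 benzoxazinoid genes, 2 fell and none rose (4 adjusted over the list alone). The median was -0.38 (camera adjusted p = 0.008; adjusted p = 0.701 with an estimated correlation). BX5 fell (log2 -1.14, SE 0.18, adjusted p = 0.00135). On that list fusarium replicate 2 differed by -0.446, and the call was lost without fusarium replicate 3 (adjusted p = 0.116). Of 17 senescence and autophagy genes, 2 rose and none fell (3 adjusted over the list alone). The median was 0.13 (camera adjusted p = 0.0056; adjusted p = 0.576 with an estimated correlation). Atg8e (GRMZM2G014975) rose from 52.2 ± 0.613 to 84.8 ± 13.5 CPM (log2 0.70, SE 0.12, adjusted p = 0.00275). The call of each of these lists except senescence was lost with fry (adjusted p = 0.15 for flavonoid, 0.134 for cell wall and 0.298 for benzoxazinoid genes).

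A further 5 lists were called as higher, but only with fusarium replicate 2 in the fit. They were photosynthesis genes (1 of 16 rose, median 0.27, camera adjusted p = 0.000382; adjusted p = 0.701 with an estimated correlation and 0.289 without that library). Redox enzymes followed (0 of 22 rose, median 0.13, camera adjusted p = 0.00592; adjusted p = 0.701 with an estimated correlation and 0.0685 without it). The others were chitinases and beta-1,3-glucanases (0 of 6, median 0.41, camera adjusted p = 0.0166; adjusted p = 0.732 with an estimated correlation and 0.289 without it), abscisic acid, dehydrin and LEA genes (1 of 19, median 0.20, camera adjusted p = 0.0166; adjusted p = 0.701 with an estimated correlation and 0.108 without it) and proteinase inhibitors (0 of 11, median 0.26, camera adjusted p = 0.0202; adjusted p = 0.701 with an estimated correlation and 0.227 without it). With fry their adjusted p ran from 0.298 to 0.496. Relative to the other fusarium libraries, replicate 2 differed by -0.771, -0.245, -0.944, -0.322 and -0.494 on these lists. The chitinase call was also lost without trichoderma_fusarium replicate 1 (adjusted p = 0.0677), the abscisic acid call without trichoderma_fusarium replicate 2 (adjusted p = 0.077) and the proteinase inhibitor call without the same library (adjusted p = 0.0715). The chitinase chiA had 1860 ± 973 CPM in fusarium and 2860 ± 361 CPM in trichoderma_fusarium silks (adjusted p = 0.449). Without fusarium replicate 2, camera with the preset correlation called 1 list as higher and 6 as lower, against 6 and 3 with it.

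Other falls were those of rth3 (GRMZM2G377215), a COBRA-like root hair gene (log2 -1.33, SE 0.23, adjusted p = 0.00224), prp2 (log2 -1.25, SE 0.21, adjusted p = 0.0069) and the auxin response factor gene ARF3 (GRMZM2G078274) (log2 -0.80, SE 0.14, adjusted p = 0.00341). CER1 (GRMZM2G066578), a different gene from the CER1 that rose with Fusarium alone, fell (log2 -0.67, SE 0.11, adjusted p = 0.00135), as did cad1 (log2 -0.73, SE 0.13, adjusted p = 0.00332). Also lower were the GAPDH genes GAPC (GRMZM2G071630) (log2 -0.58, SE 0.09, adjusted p = 0.000675) and GAPCP (GRMZM2G104632) (log2 -0.58, SE 0.09, adjusted p = 0.00135). Other rises were those of the dehydrin gene dhn1 (GRMZM2G079440) (log2 1.70, SE 0.36, adjusted p = 0.0378), the methyltransferase gene OMT8 (GRMZM2G010731) (log2 1.03, SE 0.23, adjusted p = 0.0165) and the aquaporin gene pip2c (GRMZM2G081192) (log2 0.96, SE 0.18, adjusted p = 0.0112). So were those of FBL2 (GRMZM2G153075) (log2 0.85, SE 0.11, adjusted p = 0.000298), calmodulin (GRMZM2G444621) (log2 0.81, SE 0.20, adjusted p = 0.0277) and fae1 (log2 0.51, SE 0.11, adjusted p = 0.0144). None of the 2 pollen and 4 kernel and endosperm markers was called (1 pollen marker was higher adjusted over the list alone), with medians of 0.586 and 0.571. On these lists fusarium replicate 2 differed by -0.74 and -0.347 from the other fusarium libraries. The count of 626 genes was 255, 281, 301 and 404 without trichoderma_fusarium replicate 2, fusarium replicate 1, trichoderma_fusarium replicate 1 and trichoderma_fusarium replicate 3. It was 977 without fusarium replicate 3, 629 without fusarium replicate 2, 976 with no filter and 258 in a fit of the 6 libraries compared. Of the 32 genes the naming rule gave, 19 kept their call in all alternatives. It was lost by 12 of them in the fit of the 6 libraries compared, by 9, 7 and 3 without fusarium replicates 1, 2 and 3 and by 9, 11 and 8 without trichoderma_fusarium replicates 1, 2 and 3. Without uninoculated replicates 1, 2 and 3 these were 4, 4 and 5, and without trichoderma replicates 1, 2 and 3 they were 4, 4 and 1. The genes dhn1, OMT8, pip2c, calmodulin and fae1 lost theirs in 1 or more. Their largest adjusted p was 0.151 for dhn1, 0.113 for OMT8, 0.0579 for pip2c, 0.119 for calmodulin and 0.0972 for fae1.

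The comparison of trichoderma_fusarium with trichoderma silks gave the response to Fusarium in plants whose roots had been given Trichoderma. Genes of antifungal proteins and a proteinase inhibitor were among the large rises. The chitinase gene chiA rose from 391 ± 66.4 to 2860 ± 361 CPM (log2 2.87, SE 0.39, adjusted p = 0.000496). PR-5 rose from 28 ± 2.97 to 223 ± 25.2 CPM (log2 3.00, SE 0.33, adjusted p = 6.99e-05) and MPI from 4.68 ± 3.55 to 75.2 ± 13 CPM (log2 3.98, SE 0.61, adjusted p = 0.000995). The steepest fall named here was that of whp, from 317 ± 34.9 to 29.7 ± 5.51 CPM (log2 -3.42, SE 0.19, adjusted p = 8.17e-09). In all, 4015 genes rose and 4001 fell. By 2-fold or more 1273 rose and 1044 fell.

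Other large rises were AR4 (log2 fold change 3.84, SE 0.44), GLB1 (3.19, SE 0.48), CNR2 (GRMZM2G151230) (2.94, SE 0.39) and CPPS2 (2.75, SE 0.37), with adjusted p-values from 3.15e-06 for AR4 to 7.59e-05 for CNR2. Other large falls were prp2 (log2 fold change -3.11, SE 0.21), Profilin (-3.07, SE 0.23), actin (-2.84, SE 0.11), BX5 (-2.44, SE 0.17), TUB1 (-2.28, SE 0.19) and expa2 (-2.23, SE 0.26), with adjusted p-values from 1.42e-12 for actin to 1.81e-06 for expa2. All 6 chitinases and beta-1,3-glucanases rose. The median was 2.64 (camera adjusted p = 3.21e-05; adjusted p = 0.312 with an estimated correlation). Of 5 PR proteins, 4 rose and prp2 fell. The median was 2.14 (camera adjusted p = 0.0304; adjusted p = 0.513 with an estimated correlation). Zlp rose from 116 ± 5.43 to 510 ± 72.4 CPM (log2 2.14, SE 0.22, adjusted p = 1.53e-05). Of 11 proteinase inhibitors, 7 rose and none fell (8 adjusted over the list alone). The median was 0.44 (camera adjusted p = 0.0146; adjusted p = 0.504 with an estimated correlation). Cystatin (GRMZM2G438551) rose (log2 0.55, SE 0.12, adjusted p = 0.00109). Of 17 senescence and autophagy genes, 12 rose and none fell (13 adjusted over the list alone). The median was 0.42 (camera adjusted p = 0.00011; adjusted p = 0.186 with an estimated correlation). Atg8e rose (log2 1.11, SE 0.13, adjusted p = 1.13e-06). Of 15 terpenoid phytoalexin genes, 8 rose and fps fell (9 and 1 adjusted over the list alone). The median was 0.60 (camera adjusted p = 0.00508; adjusted p = 0.204 with an estimated correlation). Of 15 jasmonate signalling genes, 4 rose and none fell. The median was 0.28 (camera adjusted p = 0.0161; adjusted p = 0.504 with an estimated correlation). TIFY27 rose (log2 1.13, SE 0.12, adjusted p = 5.56e-07). Of 19 abscisic acid, dehydrin and LEA genes, 7 rose and 2 fell. The median was 0.24 (camera adjusted p = 0.0264; adjusted p = 0.504 with an estimated correlation and 0.0547 without trichoderma_fusarium replicate 2). SnRK2.6 rose (log2 0.97, SE 0.11, adjusted p = 7.62e-07).

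Of 18 flavonoid and maysin genes, 13 fell and 1 rose (13 and 2 adjusted over the list alone). The median was -1.01 (camera adjusted p = 0.00011; adjusted p = 0.399 with an estimated correlation). The gene sm1 fell from 1100 ± 51 to 508 ± 31.5 CPM (log2 -1.11, SE 0.09, adjusted p = 3.36e-08). Of 30 cell wall genes, 20 fell and 1 rose (21 and 1 adjusted over the list alone). The median was -0.565 (camera adjusted p = 8.7e-06; adjusted p = 0.204 with an estimated correlation). CesA-4 (log2 -1.50, SE 0.11, adjusted p = 4.59e-09) and CesA-2 (GRMZM2G027723) (log2 -1.32, SE 0.10, adjusted p = 7.27e-09) fell. Of 10 benzoxazinoid genes, 6 fell and 1 rose. The median was -1.03 (camera adjusted p = 0.00594; adjusted p = 0.451 with an estimated correlation). glu1 (GRMZM2G016890), the beta-glucosidase that frees benzoxazinoids from their sugar, fell from 964 ± 131 to 264 ± 62.7 CPM (log2 -1.86, SE 0.15, adjusted p = 9.39e-08). Of 27 histone and DNA replication genes, 19 fell and 2 rose. The median was -0.60 (camera adjusted p = 0.00011; adjusted p = 0.204 with an estimated correlation). The cyclin gene cycD2 (GRMZM2G075117) rose (log2 0.71, SE 0.10, adjusted p = 1.88e-05). Of 24 reference genes, 16 fell and 4 rose. The median was -0.415 (camera adjusted p = 1.66e-05; adjusted p = 0.204 with an estimated correlation). Profilin and PRO4 (log2 -0.84, SE 0.11, adjusted p = 5.09e-06), listed as pollen markers, both fell, with a median of -1.95. Of 4 kernel and endosperm markers GLB1 rose. Of 36 ribosomal protein genes, 15 fell and 3 rose (17 and 3 adjusted over the list alone). The median was -0.29 (camera adjusted p = 0.00508; adjusted p = 0.563 with an estimated correlation and 0.0527 with fry). Of 16 photosynthesis genes, 7 fell and 1 rose. The median was -0.33 (camera adjusted p = 0.0347; adjusted p = 0.563 with an estimated correlation). This call was lost without trichoderma replicate 2 (adjusted p = 0.0611), without trichoderma_fusarium replicate 1 (adjusted p = 0.0539) and with fry (adjusted p = 0.138). The other lists were not called with camera. With fry, brassinosteroid and sterol and sugar transport genes (adjusted p = 0.00748 each), lipid transfer and cuticle (adjusted p = 0.0165) and calcium signalling genes (adjusted p = 0.0258) were called as lower. WRKY factors (adjusted p = 0.00476) and gibberellin and cytokinin genes (adjusted p = 0.0197) were called as higher. Outside the lists called with camera, lox1 (log2 -1.91, SE 0.20, adjusted p = 5.33e-06), sus1 (log2 -1.38, SE 0.10, adjusted p = 7.76e-09) and the invertase gene ivr2 (GRMZM2G089836) (log2 -1.14, SE 0.16, adjusted p = 6.69e-05) fell. So did CER1 (GRMZM2G066578, log2 -0.97, SE 0.11, adjusted p = 1.06e-06) and cad1 (log2 -2.05, SE 0.12, adjusted p = 7.66e-10). PER42 rose (log2 3.15, SE 0.49, adjusted p = 4.79e-05).

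**Figure D3:**
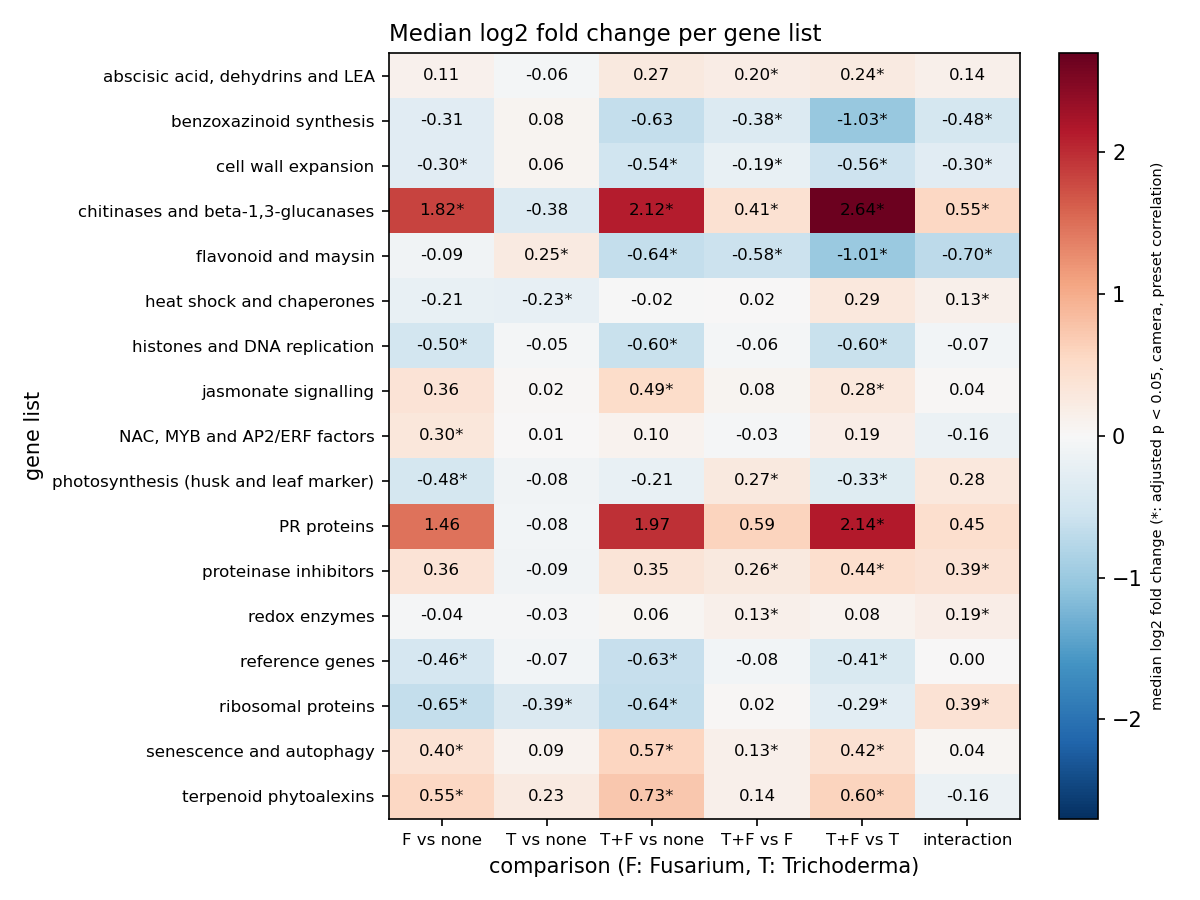
Median log2 fold change of each gene list (rows, the lists called in 1 or more comparisons) in the 6 comparisons (columns), by colour and number, an asterisk marking camera adjusted p under 0.05 with the preset correlation of 0.01. Chitinases and beta-1,3-glucanases run from -0.378 with Trichoderma alone to 2.64 with Fusarium on Trichoderma plants, and flavonoid and maysin genes reach -1.01 in the latter; no list was called with an estimated correlation.

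The interaction compared the Fusarium response with Trichoderma to that without it, so that a positive value means a greater rise or a smaller fall with Trichoderma. Of 18 flavonoid genes 6 responded more negatively in plants given Trichoderma, while 4 of 24 heat shock and 3 of 36 ribosomal protein genes responded more positively. Camera called these lists, but not with an estimated correlation (adjusted p = 0.565 each). The ribosomal protein median was -0.393 in trichoderma against uninoculated silks and 0.0239 in trichoderma_fusarium against fusarium silks. For heat shock genes these were -0.226 and 0.0203. The positive interaction of these 2 lists thus lay mostly in the difference between trichoderma and uninoculated silks. The gene sm1 had 775 ± 54.5 CPM in uninoculated and 895 ± 91.3 CPM in fusarium silks, but 1100 ± 51 CPM in trichoderma and 508 ± 31.5 CPM in trichoderma_fusarium silks (interaction log2 -1.32, SE 0.13, adjusted p = 2.14e-05). The gene whp fell with Fusarium from 216 to 76.9 CPM without and from 317 to 29.7 CPM with Trichoderma (interaction log2 -1.93, SE 0.25, adjusted p = 0.000976). Hsp70 had 216, 113, 94.2 and 122 CPM in uninoculated, fusarium, trichoderma and trichoderma_fusarium silks (interaction log2 1.31, SE 0.18, adjusted p = 0.000538). In edgeR's quasi-likelihood test 260 genes had a positive and 247 a negative interaction, and 3730 had an unadjusted p under 0.05.

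Of 18 flavonoid and maysin genes, 6 had a negative and none a positive interaction (9 adjusted over the list alone). The median was -0.70 (camera adjusted p = 1.54e-05; adjusted p = 0.565 with an estimated correlation and 0.112 with fry). The flavanone 3-hydroxylase gene f3h (GRMZM2G062396) was among them (log2 -2.06, SE 0.51, adjusted p = 0.0425). Of 30 cell wall genes, 2 were negative and none positive (10 adjusted over the list alone). The median was -0.30 (camera adjusted p = 0.000165; adjusted p = 0.565 with an estimated correlation and 0.112 with fry). The negative members were expa2 (log2 -1.67, SE 0.33, adjusted p = 0.0104) and CesA-2 (log2 -0.61, SE 0.14, adjusted p = 0.0219). Of 10 benzoxazinoid genes, 3 were negative and none positive (4 adjusted over the list alone). The median was -0.48 (camera adjusted p = 0.00447; adjusted p = 0.609 with an estimated correlation and 0.199 with fry). BX4 (log2 -1.14, SE 0.21, adjusted p = 0.00696) and BX3 (GRMZM2G167549) (log2 -0.85, SE 0.18, adjusted p = 0.0151) were negative. Of 36 ribosomal protein genes, 3 were positive and none negative (16 adjusted over the list alone). The median was 0.39 (camera adjusted p = 4.25e-12; adjusted p = 0.565 with an estimated correlation and 0.112 with fry). Positive members were rps4 (log2 0.54, SE 0.12, adjusted p = 0.0217) and RPL27A (GRMZM2G047732) (log2 0.78, SE 0.18, adjusted p = 0.0314). Of 24 heat shock and chaperone genes, 4 were positive and none negative (7 adjusted over the list alone). The median was 0.13 (camera adjusted p = 0.0048; adjusted p = 0.565 with an estimated correlation and 0.0852 with fry). The small chaperone gene hsp22 was positive (log2 2.16, SE 0.32, adjusted p = 0.00092).

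Redox enzymes were called with 0 of 22 members past the threshold. The median was 0.19 (camera adjusted p = 0.00447; adjusted p = 0.609 with an estimated correlation and 0.275 with fry). Fusarium replicate 2 differed from the other fusarium libraries by -0.245 on this list. Chitinases and beta-1,3-glucanases were called with 0 of 6. The median was 0.55 (camera adjusted p = 0.0147; adjusted p = 0.731 with an estimated correlation and 0.427 with fry). Without uninoculated replicate 1, fusarium replicate 2 or trichoderma replicate 3 their adjusted p was 0.0819, 0.0579 and 0.0704. On them fusarium replicate 2 differed by -0.944 from the other fusarium libraries. Proteinase inhibitors were called with cc7 (GRMZM2G148925), a cystatin (log2 1.02, SE 0.24, adjusted p = 0.0387), as 1 of 11 (2 adjusted over the list alone). The median was 0.39 (camera adjusted p = 0.0382; adjusted p = 0.731 with an estimated correlation and 0.427 with fry). Fusarium replicate 2 differed by -0.494 on them. Without uninoculated replicate 1, fusarium replicate 2, trichoderma replicate 1, trichoderma replicate 3 or trichoderma_fusarium replicate 2 their adjusted p was 0.136, 0.12, 0.0755, 0.0539 and 0.0624.

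Single genes with positive interactions included asn2 (log2 1.64, SE 0.24, adjusted p = 0.000976), calmodulin (log2 1.34, SE 0.27, adjusted p = 0.0124) and hsp18f (log2 1.39, SE 0.28, adjusted p = 0.0115). ZmCASPL2D1 (GRMZM2G318633) (log2 1.96, SE 0.40, adjusted p = 0.0136), Atg8e (log2 0.88, SE 0.18, adjusted p = 0.0126) and the ubiquitin gene ubiquitin (GRMZM2G118637) (log2 0.56, SE 0.12, adjusted p = 0.0151) were positive too. ERF1 (log2 -2.30, SE 0.51, adjusted p = 0.021), rth3 (log2 -1.42, SE 0.30, adjusted p = 0.0168) and CER1 (GRMZM2G066578, log2 -1.09, SE 0.15, adjusted p = 0.000537) had negative interactions. So did ARF3 (log2 -0.99, SE 0.20, adjusted p = 0.0112), GI (log2 -0.83, SE 0.16, adjusted p = 0.00776) and GAPCP (log2 -0.82, SE 0.13, adjusted p = 0.00173). No pollen or kernel and endosperm marker was called (1 pollen marker was positive adjusted over the list alone), with medians of 0.66 and 0.0328. On these lists fusarium replicate 2 differed by -0.74 and -0.347 from the other fusarium libraries. The count of 507 genes was 180, 264, 182, 240, 257 and 196 without uninoculated replicates 1 and 2, trichoderma replicates 1 and 2 and trichoderma_fusarium replicates 1 and 2. It was 745 without fusarium replicate 3, 649 without fusarium replicate 2 and 937 with no filter. Of the 34 genes the naming rule gave, 11 kept their call in all alternatives that tested them. It was lost by 19, 15, 19, 15, 15 and 15 of them without the first 6 of these libraries. Without uninoculated replicate 3, fusarium replicates 1, 2 and 3, trichoderma replicate 3 and trichoderma_fusarium replicate 3 these were 4, 7, 4, 2, 4 and 6.

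**Figure D4:**
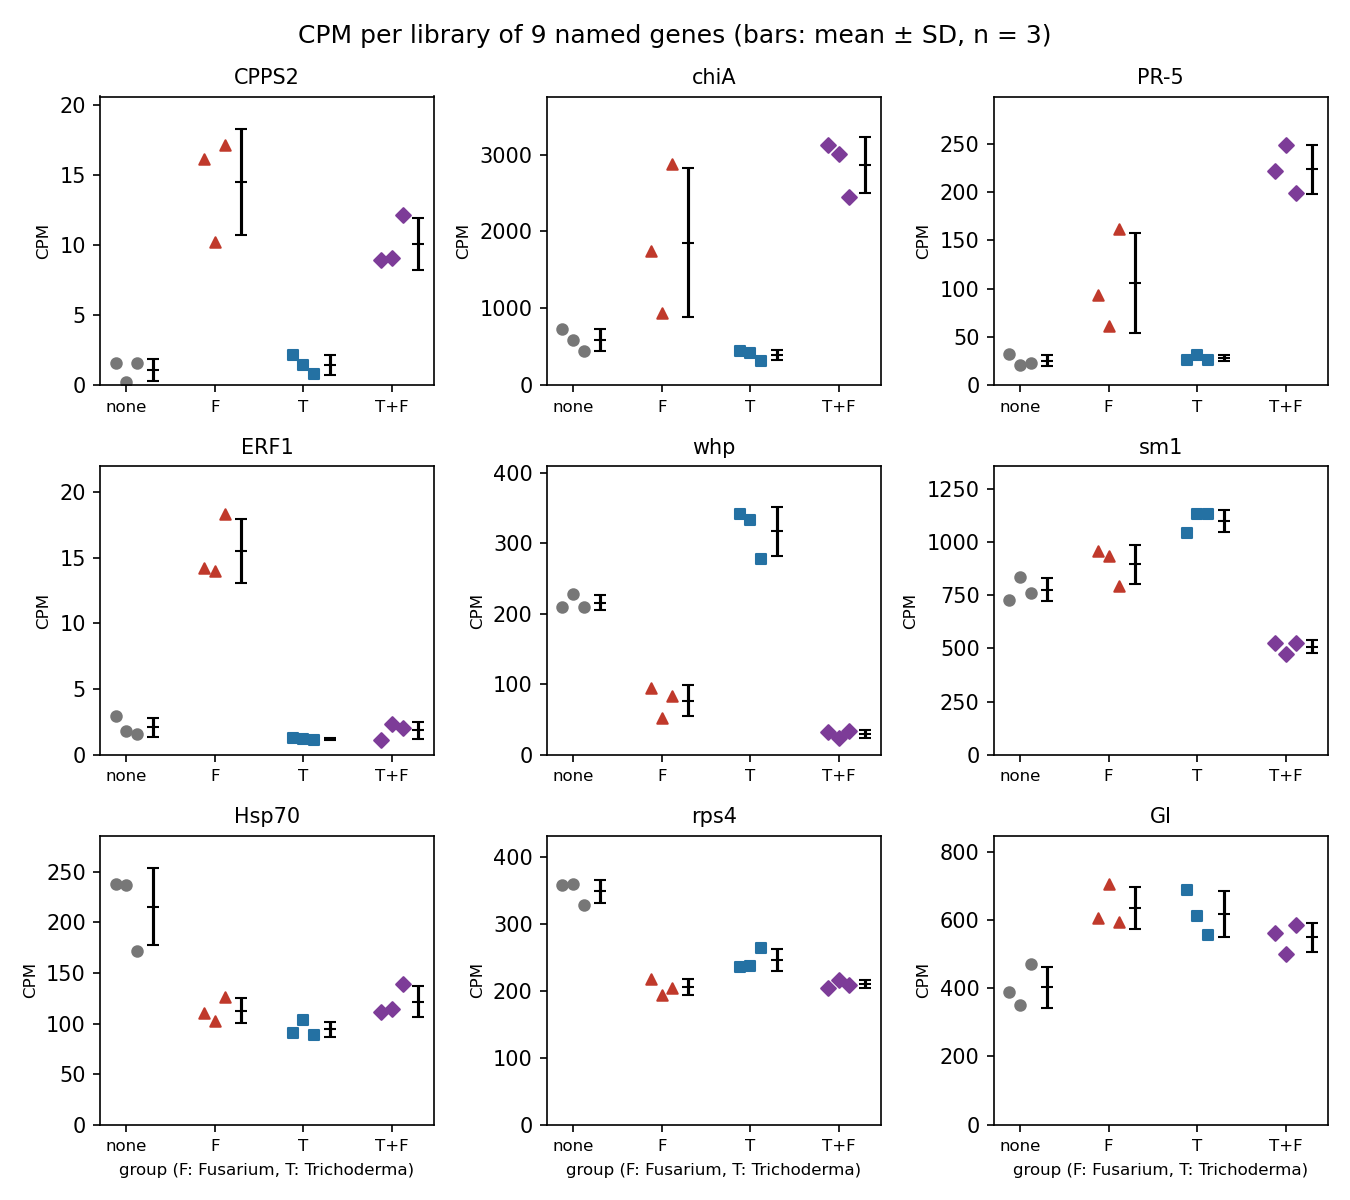
CPM (vertical axes, starting at 0) of 9 named genes in each library of the uninoculated (none), fusarium (F), trichoderma (T) and trichoderma_fusarium (T+F) groups, with the mean and SD of 3 libraries beside the points. ERF1 stands at 15.5 CPM in fusarium and at 1.86 CPM in trichoderma_fusarium silks, and whp at 317 CPM in trichoderma and 29.7 CPM in trichoderma_fusarium silks.

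The Fusarium responses without and with Trichoderma, which share no library, correlated across the 20517 genes with Pearson's r 0.742 (Spearman 0.702); genes are not independent replicates. Of the genes called in both, 2482 rose in both (809 from independent lists), 2626 fell in both (793), and 28 and 31 moved in opposite directions (807 and 796). CPPS2, chiA and MPI rose and actin, Profilin and whp fell in both. The Trichoderma responses without and with Fusarium, which also share no library, correlated with Pearson's r 0.0186 (Spearman -0.0777). Of the genes called in both, 15 rose in both (3.45 from independent lists), 7 fell in both (4.3), 14 rose without and fell with Fusarium (3.41) and 9 did the reverse (4.36). The gene sm1 was among those higher without and lower with Fusarium.

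The responses to Fusarium alone and to Trichoderma alone share the uninoculated libraries. Their correlation was 0.433 (Spearman 0.475), against a mean of 0.51 (0.486 to 0.528) over 20 draws of unchanged groups set against those controls. Their covariance was 0.11, against 0.0376 (0.0345 to 0.0407) in the draws, a difference of 0.0724. The draws treat genes as independent, so shifts shared by many genes in the control libraries are not in them. The difference therefore does not establish a common response. Of the genes called in both, 146 rose in both (45.4 from independent lists) and 234 fell in both (56.3). Hsp70, hsp22 and rps4 fell in both, while 13 and 9 moved in opposite directions (57.3 and 44.6). The 3 control libraries cannot be split into parts of at least 2 each, so what the shared controls add was not measured a second way.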

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

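The tests of other splits of the libraries, of relabelled groups, of left-out libraries, of scaling, of the amount of Fusarium and of the trend of fusarium replicate 2 below were chosen only after the results were seen, while those of library size and of reads shared between c2 and whp were written before their results.

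The Fusarium response differed between plants with and without Trichoderma, by the test of the interaction itself, for 507 genes. Among the other 99 of 100 relabellings of Trichoderma status within Fusarium status the highest count was 227, and only the real one called 507. The other relabellings mix groups that differ, which widens the spread within them and lowers their counts. They therefore cannot exclude chance. For the pairwise comparisons the 10 splits of 6 libraries are too few for a share under 0.05; the real counts were 8205, 509, 9053, 626 and 8016 and the highest count of any other split was 0 in each. The list medians of the interaction were -0.476 for benzoxazinoid synthesis, -0.302 for cell wall expansion, 0.551 for chitinases and beta-1,3-glucanases, -0.703 for flavonoid and maysin genes, 0.134 for heat shock and chaperones, 0.393 for proteinase inhibitors, 0.189 for redox enzymes and 0.389 for ribosomal proteins. Each was called with camera's preset correlation and none with an estimated one.

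Named genes whose response differed in the positive direction were MYBE1 (3), PER42 (2.85), hsp22 (2.16), ZmCASPL2D1 (1.96), asn2 (1.64), hsp18f (1.39), calmodulin (1.34), Hsp70 (1.31), PLTZ9 (GRMZM2G094168) (1.28), cc7 (1.02), Atg8e (0.88), RPL27A (0.78), PYL9 (GRMZM2G048733) (0.74), fae1 (0.65), ubiquitin (0.56) and rps4 (0.54). Those in the negative direction were ERF1 (-2.3), f3h (-2.06), whp (-1.93), expa2 (-1.67), rth3 (-1.42), sm1 (-1.32), CYP727A4 (GRMZM2G022947) (-1.27), thi1-2 (-1.17), BX4 (-1.14), CER1 (GRMZM2G066578; -1.09), ARF3 (-0.99), BX3 (-0.85), GI (-0.83), GAPCP (-0.82), ARF23 (GRMZM2G441325) (-0.75), cad1 (-0.73), NAC61 (-0.65) and CesA-2 (-0.61). Of these 34 genes 23 lost their call in 1 or more alternatives.

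Silks of Trichoderma plants lay further along the direction of the Fusarium response. On a score of each library along the mean difference between groups with and without Fusarium, uninoculated libraries had -0.514, -0.622 and -0.527, trichoderma libraries -0.445, -0.401 and -0.49, fusarium libraries 0.375, 0.411 and 0.489 and trichoderma_fusarium libraries 0.572, 0.567 and 0.586, a difference of 0.129 (SE 0.0273) for Trichoderma. Of 400 relabellings 2 gave as large a difference (exact p = 0.005, the smallest they can give). That p makes no allowance for the choice of this pattern after the results were seen, so chance stays open. The lowest difference with a library left out was 0.107, which argues against 1 library. With all libraries thinned to 3872388 counts the difference was 0.13, which argues against library size. Across genes, the Trichoderma responses without and with Fusarium correlated with Pearson's r 0.0186 (Spearman -0.0777). The Fusarium inoculation cannot account for the difference of 0.109 (SE 0.0385) between trichoderma and uninoculated silks, neither given Fusarium. Any Fusarium already present in these was not measured, because no fungal counts were used. For the difference of 0.15 between trichoderma_fusarium and fusarium silks, more Fusarium in the silks cannot be told apart for the same reason. An effect of root Trichoderma on the silks, and handling or time of collection, for which the labels give no batch, stay open and untested.

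A negative interaction was found for 6 of 18 flavonoid and maysin genes, and the list mean had one of -0.654 (SE 0.191). The list was called with camera's preset correlation, but not with an estimated one (adjusted p = 0.565) or with fry (adjusted p = 0.112). Of 400 relabellings 4 gave as large a value for this list (exact p = 0.01), which makes no allowance for its choice from 28 lists after the results were seen. In 52 of the 400 some list had as large a t (exact p = 0.13), so chance stays open. The value closest to 0 with a library left out was -0.548, which argues against 1 library. Over the other scalings the list median closest to that of all genes was -0.699 (all genes -0.0114). A change of scaling moves both medians nearly alike, so this comparison could not decide about scaling. Reads shared between c2 and whp were tested by summing their counts, and the sum had an interaction of -1.1 (SE 0.262). An effect of root Trichoderma on the Fusarium response of these genes, and a difference in handling between groups, stay open and untested.

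Ribosomal protein and heat shock genes had higher list means in uninoculated than in trichoderma silks, with trichoderma minus uninoculated of -0.342 (SE 0.0955) and -0.291 (SE 0.0502); neither list was called with an estimated correlation (adjusted p = 0.383 and 0.329). Against uninoculated silks camera did not call heat shock genes in fusarium (adjusted p = 0.204) or trichoderma_fusarium silks (adjusted p = 0.208), but fry did (adjusted p = 0.00775 and 0.00664). Camera with the preset correlation called the 11 genes with hsp symbols as lower in both (adjusted p = 0.0196 and 0.0223; adjusted p = 0.621 and 0.536 with an estimated correlation). The list means of trichoderma_fusarium replicate 3 and uninoculated replicate 3 were both 5.45. The values closest to 0 with a library left out were -0.319 and -0.271, the trend that sets fusarium replicate 2 apart would give -0.0281 and 0.00171, and over the other scalings the medians closest to that of all genes were -0.391 and -0.192 (all genes 0.00904). The left-out values argue against 1 library, and the trend values against that trend, for both lists. A change of scaling moves the list medians and that of all genes nearly alike, so their comparison could not decide about scaling. A response to Trichoderma, and a difference between the groups in time of collection or in handling, both stay open and untested; the clock genes GI and gigz1b rose in fusarium, trichoderma and trichoderma_fusarium silks against uninoculated ones.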

How the results depend on the processing

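The alternatives of scaling, filter, model and left-out library had been planned, and only the overlaps with each library left out were added after the results were seen. The counts of changed genes for fusarium against uninoculated, trichoderma_fusarium against uninoculated and trichoderma_fusarium against trichoderma stayed within 1.5 times of 8205, 9053 and 8016 in all alternatives (6326 to 8393, 7600 to 10052 and 6559 to 9162). The Fusarium responses without and with Trichoderma correlated positively in all alternatives run. So did the responses to Fusarium alone and to Trichoderma alone, but these share the uninoculated libraries. Draws of unchanged groups against those controls also correlated, at 0.486 to 0.528, so the positive sign does not establish a common response. The correlation of the Trichoderma responses without and with Fusarium took either sign. The other counts moved more. With no filter they were 802 (trichoderma against uninoculated, otherwise 509), 976 (trichoderma_fusarium against fusarium, otherwise 626) and 937 (interaction, otherwise 507). With only the 2 groups in the fit, trichoderma against uninoculated gave 1088 and trichoderma_fusarium against fusarium 258. With 1 library left out they ran from 79 (without trichoderma replicate 2) to 1141 (without fusarium replicate 2), from 255 (without trichoderma_fusarium replicate 2) to 977 (without fusarium replicate 3) and from 180 (without uninoculated replicate 1) to 745 (without fusarium replicate 3). Fewer libraries leave fewer degrees of freedom, which does not account for the counts that rose. The spread behind each test came from all groups in the fit. Libraries outside a comparison therefore also changed its count, as fusarium replicate 2 did for trichoderma against uninoculated silks. Beyond this the cause was not tested. The replicate number as a block gave 218, 395 and 240 genes. The numbers pair nothing in the labels: residuals of libraries with the same number correlated from -0.24 to 0.2, and 4 of 12 libraries correlated best with their own number.

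Gene lists called with the preset correlation numbered 9, 3, 9, 9, 14 and 8 in the 6 comparisons in the order of the report; with an estimated correlation they were 0, 0, 0, 0, 0 and 0. With fry they were 2 for trichoderma against uninoculated, 20 for trichoderma_fusarium against uninoculated, 1 for trichoderma_fusarium against fusarium and 0 for the interaction. With DESeq2 size factors they were 6 for trichoderma against uninoculated. With 1 library left out they ran from 4 (without uninoculated replicate 2) to 6 (without fusarium replicate 2) for trichoderma against uninoculated and from 8 (without trichoderma_fusarium replicate 2) to 14 (without uninoculated replicate 2) for trichoderma_fusarium against uninoculated; the cause was not tested. No named gene changed direction in any alternative that tested it. Those that kept their call in all alternatives that tested them were 68 of 71, 8 of 33, 68 of 69, 19 of 32, 66 of 67 and 11 of 34. Some alternatives did not test every named gene: without the 20 most abundant genes, 67 of the 69 and 65 of the 67 were tested. At depths of 3872388 to 6075848 counts the filter left 20517 genes, against 22562 with at least 1 CPM in 3 or more libraries and 30928 with no filter.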

Other observations

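Families of genes that share a symbol stem were tested beside the lists, a test planned before the values were seen but restated by symbol. The cesa family, 10 cellulose synthase genes, had a median log2 fold change of -0.86 and 8 members down in trichoderma_fusarium against trichoderma silks (camera adjusted p = 1.09e-05; adjusted p = 0.494 with an estimated correlation) and -0.569 with 5 down against uninoculated silks (camera adjusted p = 0.00527; adjusted p = 0.536 with an estimated correlation). In trichoderma against uninoculated silks its median was 0.24 with no member past the threshold (camera adjusted p = 0.000211; adjusted p = 0.731 with an estimated correlation), and in the interaction -0.433 with 1 member down (camera adjusted p = 7.05e-06; adjusted p = 0.553 with an estimated correlation). Of 11 genes of the kin family, 8 fell and 1 rose in trichoderma_fusarium against trichoderma silks (median -1.11, camera adjusted p = 0.0193; adjusted p = 0.494 with an estimated correlation). The hak family, 15 potassium transporter genes, had a median of 0.231 in trichoderma against uninoculated silks with no member past the threshold (camera adjusted p = 0.0194; adjusted p = 0.731 with an estimated correlation). Of 17 auxin response factor genes of the arf family, 7 fell and 1 rose in trichoderma_fusarium against trichoderma silks (median -0.258, camera adjusted p = 0.0302; adjusted p = 0.494 with an estimated correlation), and in the interaction 3 were negative (median -0.183, camera adjusted p = 0.0168; adjusted p = 0.592 with an estimated correlation).

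Fusarium replicate 2 differed from the other fusarium libraries by -0.944 in the median of chitinases and beta-1,3-glucanases, by -0.0277 in that of senescence and autophagy genes, by -0.028 in that of terpenoid phytoalexin genes and by 0.289 in that of clock genes. The table held 154 microRNA precursor IDs, which were treated as the other IDs. Across all genes tested the main effects of Trichoderma and of Fusarium correlated with 0.325 (slope 0.128).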
